A study of Gallus gallus with 6 samples.

How the data were processed

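Total RNA was measured on 6 Affymetrix chicken arrays: adipose tissue (1), liver (1) and mixes 1 to 4, which the labels give as 1 tissue, mix, without naming what each holds. Per the labels' protocols, 21 tissues were isolated from male Arbor Acres chickens at 49 days (7 weeks) of age; RNA was taken up with Trizol and labelled as biotin cRNA. Whether a sample holds 1 bird or several is not given in the sources used here. The authors computed the values with MAS5, and the deposited values are signal intensity on the linear scale; the version and the scaling target of MAS5 are not given in the sources used here. The deposited arrays were not at 1 common level. The text field that describes each sample names adipose tissue for all 6 arrays, so groups were taken from the sample titles.

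Of 38535 deposited probe sets 96 Affymetrix controls were left out. The choices that follow were made before the data were examined, except where said. Values were turned into log2(value + 13), where 13 is the 25th percentile of all values pooled over the arrays, and a probe set was tested if it exceeded the pooled median of 44.1 on at least 1 array. That left 25958 and excluded 12481. No further scaling was applied. Probe sets were named from the platform's gene annotation: of 27355 probe sets with a gene, 27178 had 1 symbol and 177 had several, and only the former were named; 11180 deposited probe sets have no listed gene. Of those with 1 symbol 26863 were matched by gene number to the reference table and 315 were not, and no symbol changed. For a gene with several probe sets the one with the highest mean over the 6 arrays was used, which gave 11653 genes. Other probe sets of a gene can give smaller or opposite differences, and some of these are given. Signal over background takes the place of depth: a probe set near 13 differs little on this scale, so a difference against such a floor depends on the pseudocount.

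Adipose against the mixes and liver against the mixes were tested with limma 3.58.1 in R 4.3.3 (1 mean per group, eBayes with a trend, Benjamini-Hochberg at 0.05, two-sided). Since adipose and liver have 1 array each, the residual spread is that among the 4 mixes alone (3 degrees of freedom, with 2.59 prior degrees of freedom), and the lone array is assumed to vary like the mixes. An exact permutation test of 1 array against 4 cannot go below 0.2 one-sided or 0.4 two-sided, so none was used. Adipose was compared with liver by size alone, at least 4-fold (log2 2). Adipose-prominent and liver-prominent probe sets are those at least 4-fold above the highest of the other 5 arrays, again without a test. In a mix a gene of 1 tissue is diluted by the others, in shares that are not given. A margin over a mix therefore does not show that each tissue in it is fainter. In all 31 gene lists were fixed, 17 of them for tissues: adipocyte genes, hepatocyte plasma proteins, complement, de novo fatty acid synthesis, triglyceride storage and lipolysis, cholesterol synthesis, fatty acid oxidation and ketogenesis, bile acid and xenobiotic metabolism, amino acid catabolism and gluconeogenesis, liver transcription factors, estrogen-induced yolk proteins, skeletal muscle, heart, smooth muscle, brain, intestine, pancreas, glandular stomach, kidney, lymphoid, macrophage and myeloid, testis, endocrine glands, lung, erythrocyte, endothelium, fibroblast and matrix, skin keratinocyte, mitochondrial respiration, ribosomal proteins and cell cycle. Some genes stand in more than 1 list. The lists were tested with limma's camera (preset correlation 0.01, adjusted over the 31 lists per comparison), and again with the correlation estimated for each list: 16 lists passed for each of the comparisons with the mixes, and none with the estimated correlation (3 and 6 at an unadjusted p under 0.05). For adipose minus liver a list's median was placed among those of 10000 random lists of the same size and like expression.

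Genes were named by rule: the 10 largest increases and 6 largest decreases for each comparison with the mixes, among those that passed and lay outside the range of the mixes, then by size; the 8 largest each way for adipose against liver; the 10 widest margins of each prominent set; up to 4 members of a list per comparison; the 3 widest margins of each mix; and FABP4, PPARG, LPL, PLIN1, ADIPOQ, ALB, FASN, SCD, APOA1 and FGB. The members of the prominent sets listed by group are those counted. On simulated data with the spread of the mixes, 50 changes of each size among 25958 probe sets, limma called 10% of changes of log2 2, 66% of 4, 94% of 6 and 98% of 8, with 14 unchanged probe sets called; the 4-fold rule found 28%, 98%, 100% and 100%, with 53 unchanged ones. With a smaller spread limma called 94% of changes of log2 2 and all larger ones, with 12 unchanged probe sets called. The 4-fold rule then found 16% of changes of log2 2 and all larger ones, with 0 unchanged ones. The simulated values were independent and normal, with the same spread on every array. On the real arrays single mixes stand apart and genes of many lists move together. The shares called are therefore not the power of the test on these data.

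Alternatives tried were the pooled 10th percentile (3) or median (44) as the pseudocount, a floor at the pooled median, no filter, quantile normalization, eBayes without a trend, a 2-fold minimum beside the test, thresholds of 2-fold and 8-fold, limma for adipose against liver, the prominent sets against the mixes alone, the mean of all probe sets of a gene, and leaving out each mix in turn. Scaling to a mean trimmed by 2% and to the 27 hybridisation spike-in probe sets were added after the levels of the arrays had been seen. Splits of the samples into other groups were not counted, since adipose and liver have 1 array each. The overlap of the adipose and liver differences from the mixes was left out, since both share the same 4 arrays. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.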

Results

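Chicken tissues were measured on 6 Affymetrix arrays: 1 of adipose tissue, 1 of liver and 4 of mixed tissues, called mix 1 to mix 4 here, all from male Arbor Acres birds, a meat-type line, at 49 days of age. The question was which genes stand out in adipose tissue and in liver when set against 4 mixes of tissues whose content the labels do not name. Since a mix dilutes each of its tissues, a difference from the mixes is not a difference from every tissue in them. The median signal over 38439 probe sets was 48 on adipose, 27 on liver and 49.4, 45.8, 44.8 and 58.1 on mix 1, 2, 3 and 4, in intensity units. On the log2 scale the median of the 25958 probe sets tested was 0.08 above the mean of the mixes on adipose and lay at -0.75 on liver, while the hybridisation spike-ins lay at 0.14 and -0.12. The deposited scaling was kept, and values for liver are also given relative to that -0.75. With another scaling the shift was -0.06 (quantile), -0.25 (trimmed mean) or -0.64 (spike-ins) on liver, and -0.01, -0.11 or -0.04 on adipose. The limma p-values set a lone array against the spread among the 4 mixes alone. Camera's p-values at the preset correlation of 0.01 treat the genes of a list as nearly independent. Neither carries a spread of adipose or of liver, with 1 array each, which limits their precision. The labels also do not name separate birds.

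**Figure D1:**
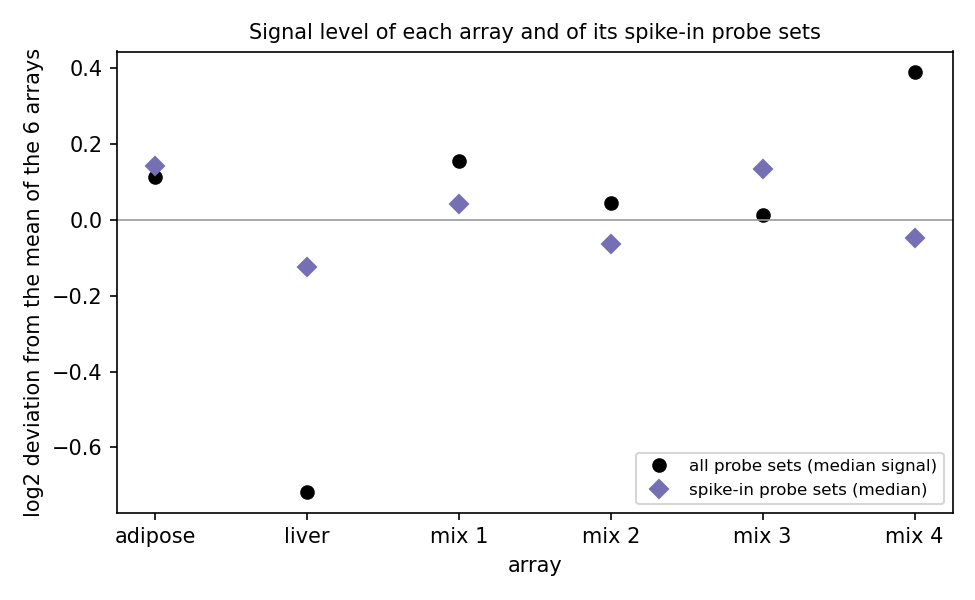
Log2 median signal of each of the 6 arrays relative to the mean of all 6, for all 38439 probe sets and for the 27 hybridisation spike-in probe sets. The liver array sits at -0.72 for all probe sets and at -0.12 for the spike-ins.

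The mixes carried different tissue genes. Mix 1 was brightest for intestine and stomach genes: the median log2 level of the 28 intestine genes was 11.99 there against 5.37 to 6.73 on the other mixes, and that of the 9 glandular stomach genes 12.55 against 5.27 to 8.51. CLCA1, made by goblet cells, gave a signal of 9767 on mix 1 and at most 41.2 elsewhere, with RBP2 at 7212 and the proton pump subunit ATP4B at 5971. Smooth muscle genes were also highest there (11.25 against 7.84 to 8.87). Mix 2 was brightest for the 18 pancreas genes, such as the digestive enzymes CPA1 (18291) and PRSS2 (12492), with a median of 13.63 against 5.08 to 8.43, and for kidney (8.35 against 5.19 to 6.04) and heart (7.75 against 5.12 to 5.61). The genes that led mix 2 by the widest margin were C6orf58 (5719), MUC4L (4168) and AVDL (7979). Mix 3 led in red-cell genes (11.78 against 6.06 to 9.16) and cell cycle genes (9.13 against 8.02 to 8.23), and its widest margins were those of the cartilage genes MATN1 (5648) and LECT1 (9153) and of C17orf67 (5015). Mix 4 led in brain genes (10.18 against 5.63 to 6.03), with the synaptic genes SNAP25 at 8799, SYP at 3017 and GRIN1 at 2402, and in skeletal muscle genes (10.64 against 5.08 to 7.61). The 28 testis genes (7.20 on mix 2 and 7.53 on mix 4, against 5.30 to 5.51) and the 6 endocrine gland genes (9.39 and 9.36, against 5.41 to 5.54) were high on 2 mixes alike. Of the latter CYP17A1 gave 6114 and 5704 there and at most 9.1 on the other mixes. Across probe sets, which are not independent replicates, Pearson's r between 2 mixes was 0.710 to 0.827 (mean 0.783, SD 0.0396 over 6 pairs), against a mean of 0.798 between adipose and the mixes and 0.746 between liver and the mixes. The median SD over the 4 mixes was 0.48 on the log2 scale, against 0.13 for the spike-ins, and 16.6% of probe sets had an SD over 1. The spike-ins were taken as log2 signal without the added 13, and all lie at 86.2 or more. They have no counterpart to the fainter probe sets, so these SDs are not like for like.

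**Figure D2:**
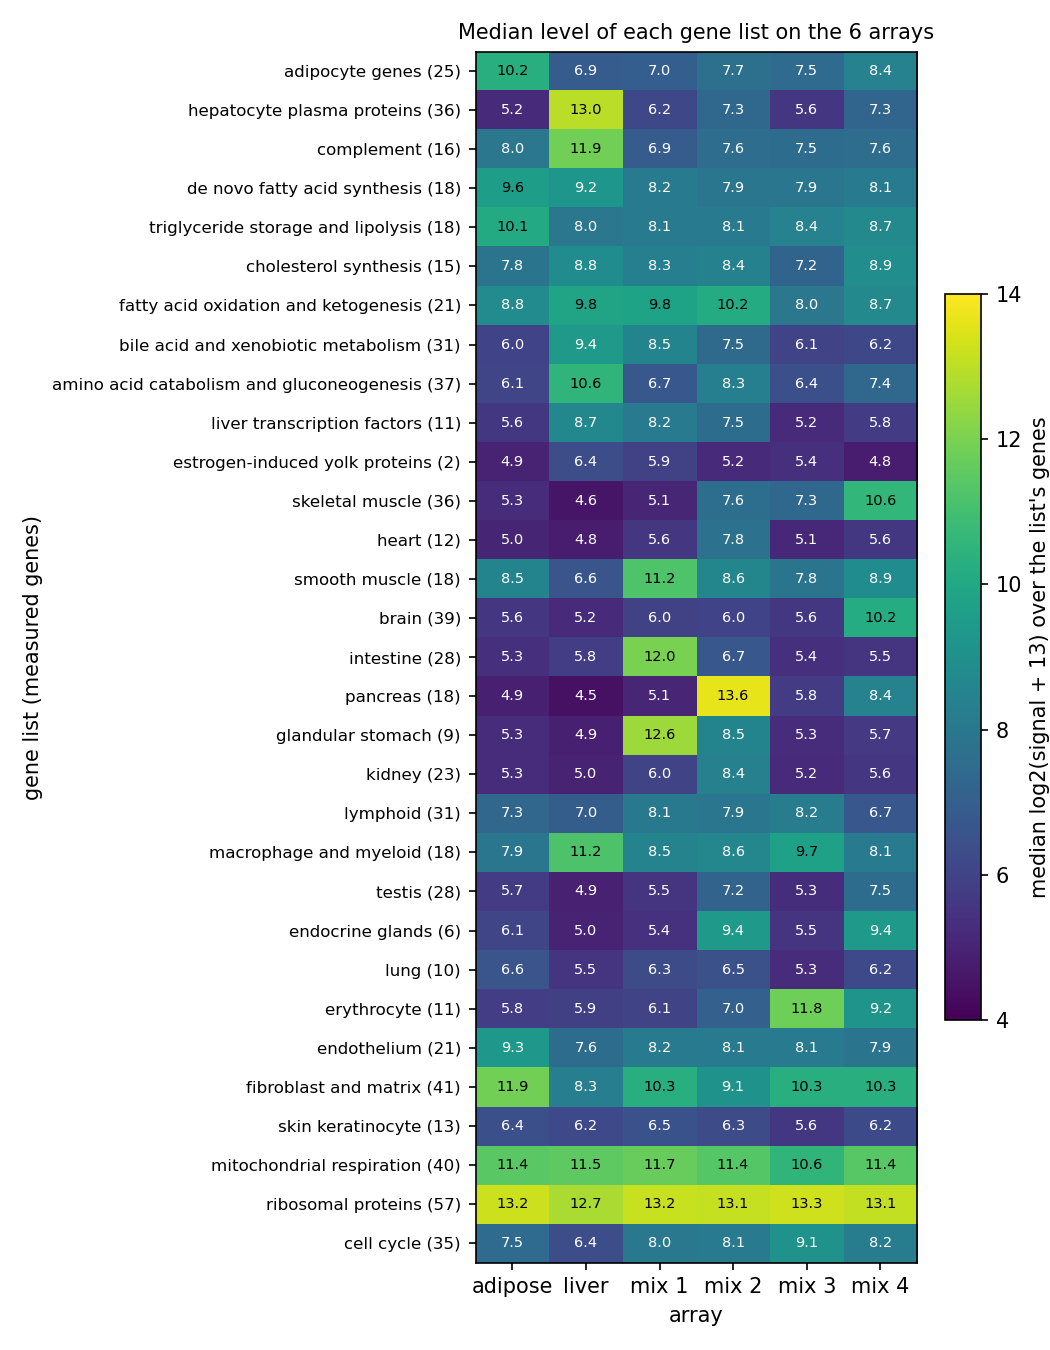
Median log2 signal of the genes of each of the 31 gene lists on each of the 6 arrays, with 1 cell per list and array. The mixes lie apart for tissue lists such as pancreas (13.63 on mix 2) and brain (10.18 on mix 4) and together for ribosomal proteins (13.10 to 13.26).

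The largest differences of adipose tissue from the mixes included genes of fat storage. PLIN1, which coats the lipid droplet, gave a signal of 11033 on adipose against 301 ± 249.7 on the mixes (mean ± SD, n = 4), a log2 difference of 5.48 (SE 1.01). THRSP, a regulator of lipogenesis, gave 13564 against 245 ± 182 (6.09, SE 1.11), the desaturase SCD 1591 against 21.2 ± 15.6 (5.67, SE 0.65), and LPL, which frees fatty acids from circulating triglyceride, 10403 against 456 ± 239 (4.61, SE 0.66). The retinol carrier RBP7 (5.26, or 0.80 by its other probe set), the fatty acid carrier FABP4 (4.14) and PPARG, the factor that drives adipocyte differentiation (3.91), were also above all 4 mixes, as was FASN (2.28). None of these passed a test: by limma 0 of 25958 probe sets had an adjusted p under 0.05 (1904 at an unadjusted p under 0.05, smallest adjusted p = 0.211). Differences of single genes are therefore given as values. ADIPOQ, the adipose hormone adiponectin, was an exception in size: 4236 on adipose and 4824 on mix 1, against 651 to 803 on mix 2, 3 and 4. Other large differences were those of C4A, a complement component (5.61 by the brighter of its 2 probe sets, under 4-fold by the other), C12orf75 (5.49), C27H17ORF105 (5.40), HPS4 (5.05), the collagen COL28A1 (5.02, 3.05 by the lowest of its 3 probe sets) and LOC100858647 (4.98), all above all 4 mixes. C4A, by that brighter probe set, and LOC100858647 were about as bright on liver (7549 and 11675) as on adipose (8453 and 11383). APOA1 was bright everywhere, at 10655 on adipose and 4319 to 12477 on the mixes.

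As lists, fat-cell, vessel and matrix genes were higher on adipose than other genes were, and the lung genes SFTPA2 (4.50), HOPX (4.48) and SFTPA1 (4.25) stood high there too, which leaves the tissue behind the vessel and matrix values open. Of 25 adipocyte genes, 17 lay above all 4 mixes and 0 below, with a median difference of 2.36. By limma 12 passed when adjusted over the list alone and 0 over all probe sets (camera adjusted p = 6e-10, and adjusted p = 0.164 with an estimated correlation). The list covers PLIN1, THRSP, RBP7 and LPIN1 (4.67). Of 18 genes of triglyceride storage and lipolysis, which share members with it, 11 lay above all mixes (median 1.09, with CIDEC at 4.58). Of these genes 9 passed when adjusted over the list alone and 0 over all (adjusted p = 1.67e-05, or 0.164 with an estimated correlation). Of 21 endothelial genes 18 lay above all mixes, with a median of 1.64: PECAM1 3.58, FABP5 3.48, CDH5 2.62 and CLDN5 2.61. Of them 11 passed when adjusted over the list alone and 0 over all (adjusted p = 3.21e-13, or 0.107 with an estimated correlation). Of 41 fibroblast and matrix genes 24 lay above all mixes (median 1.09), led by PI16 (4.39, or 1.15 by its other probe set), MFAP5 (3.95), the crosslinking enzyme LOX (2.98) and OGN (2.73). Of these genes 4 passed when adjusted over the list alone and 0 over all (adjusted p = 6.44e-09, or 0.631 with an estimated correlation). De novo fatty acid synthesis was split, with 7 of 18 genes above all mixes, 2 below, and 5 past the test when adjusted over the list alone and 0 over all (adjusted p = 0.0337, or 0.769 with an estimated correlation). Its median of 0.16 turned to -0.05 with trimmed-mean scaling and stood at 0.37 without mix 2 and 0.39 without mix 4. ACACB, an acetyl-CoA carboxylase, stood at 3.44 there, or 1.28 by the lowest of its 3 probe sets.

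Lower on adipose were the lists of cell cycle, skeletal muscle, heart, plasma protein, bile acid, pancreas, intestine, glandular stomach, kidney, red-cell and brain genes. Of 35 cell cycle genes 29 lay below all 4 mixes (median -0.94, TYMS -2.28, RRM2 -1.84, adjusted p = 2.57e-10, or 0.769 with an estimated correlation). All 36 skeletal muscle genes were lower than the mean of the mixes and 13 lay below all mixes, with a median of -2.52 (adjusted p = 1.55e-07, or 0.769 with an estimated correlation). MB, the oxygen store of muscle, gave 2.1 against 81.9 to 11646 (-6.35), and MYL3, at 2.7 on adipose and 0.8 on mix 1, stood at -4.55. The 36 plasma protein genes of hepatocytes had a median of -1.03 (adjusted p = 3.83e-06, or 0.646 with an estimated correlation), with APOA4 at -4.97, ALB at -3.38 and FGB at -3.16. Pancreas (-3.14, adjusted p = 0.0014, or 0.769 with an estimated correlation), intestine (-1.92, adjusted p = 0.00219, or 0.783 with an estimated correlation) and kidney genes (-1.34, adjusted p = 0.00219, or 0.769 with an estimated correlation) were lower too, with 8 of 18, 11 of 28 and 10 of 23 genes below all mixes. Examples were CPA1 at -4.24, FABP1 at -5.16 and CALB1 at -4.16 (-1.74 by its other probe set), while the water channel AQP3 of the kidney list stood at 4.67. Also lower were red-cell genes (-1.65, adjusted p = 0.00723, or 0.769 with an estimated correlation), brain genes (-1.33, adjusted p = 0.00176, or 0.783 with an estimated correlation) and genes of bile acid and xenobiotic metabolism (-0.96, adjusted p = 0.00982, or 0.783 with an estimated correlation). Heart (-1.51, adjusted p = 0.0344, or 0.769 with an estimated correlation) and glandular stomach genes (-1.95, adjusted p = 0.0448, or 0.783 with an estimated correlation) came last. None of these genes passed limma alone, and none passed when adjusted over its list. Among single genes the lowest included the peptidase MME, at 15.4 against 1174 to 2579 (-5.90, adjusted p = 0.211), MYL10 (-5.19) and PCK1, a key enzyme of gluconeogenesis (-5.13). MME passed with the floor alone (0.0205, range over the alternatives 0.0205 to 0.627). Values of single genes faint on adipose depend on the pseudocount. Floored at 44.1, MME stood at -5.26, MB -4.75, MYL10 -4.50, FABP1 -3.88, APOA4 -3.86, PCK1 -3.70, MYL3 -3.45, CPA1 -2.92, CALB1 -2.77 and FGB -2.74. Single mixes carried much of the medians of these lists. Without mix 1 the median was -0.49 for intestine, -0.83 for glandular stomach and -0.55 for bile acid metabolism. Without mix 2 it was -1.51 for pancreas, -0.82 for kidney and -0.77 for heart. It was -0.61 for red-cell genes without mix 3 (-2.51 without mix 1), and -0.31 for brain and -1.39 for skeletal muscle without mix 4. Calls ended for bile acid (0.0812; range over the alternatives 0.000815 to 0.0812) and glandular stomach (0.148; 0.0103 to 0.148) without mix 1, heart (0.354; 0.00636 to 0.354) without mix 2, fatty acid synthesis (0.15; 0.0103 to 0.15) without mix 3 and brain (0.0766; 0.000256 to 0.0766) without mix 4. With trimmed-mean scaling these lists other than fatty acid synthesis, and kidney (0.0658, range 0.000259 to 0.0658), did not pass either. Heart also did not pass with the floor (0.116), quantile (0.171) and spike-in scaling (0.0784), nor glandular stomach with these (0.137, 0.0747 and 0.0873) and with the median as pseudocount (0.0517). The same held for bile acid with quantile scaling (0.0542) and fatty acid synthesis with the floor (0.0522).

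The other 15 lists did not pass on adipose against the mixes, and camera's adjusted p is given with its range over the alternatives where 1 of these passed. Lung genes came close (median 0.54, adjusted p = 0.052, range 0.0243 to 0.0765). They passed with quantile, trimmed-mean and spike-in scaling (0.0243, 0.0297 and 0.0258), without the filter (0.041), without mix 1 (0.0369) and without mix 2 (0.0437). SFTPA2 stood at 4.50, SFTPA1 at 4.25 and HOPX, which other tissues make too, at 4.48. Lymphoid genes had a median of -0.31 (adjusted p = 0.052, range 2.54e-06 to 0.26, passing without mix 4 at 2.54e-06). Testis genes had -0.79 (adjusted p = 0.0559, range 0.00402 to 0.401, passing without mix 1 at 0.00402, without mix 3 at 0.0281, without the filter at 0.0387 and with the mean of all probe sets at 0.0271). Without mix 3, genes of amino acid catabolism (-0.51, adjusted p = 0.074, range 0.0136 to 0.412), cholesterol synthesis (-0.60, adjusted p = 0.132, range 0.00787 to 0.355) and liver transcription factors (-1.37, adjusted p = 0.196, range 0.0305 to 0.457) passed at 0.0136, 0.00787 and 0.0305. Endocrine gland genes (-2.07, adjusted p = 0.102, range 0.0243 to 0.411) passed without mix 1 at 0.0243. Yolk proteins (-0.39, adjusted p = 0.239), smooth muscle (-0.04, adjusted p = 0.485), complement (0.36, adjusted p = 0.784) and fatty acid oxidation (-0.03, adjusted p = 0.796) were far from the threshold. So were mitochondrial respiration (0.19, adjusted p = 0.444), ribosomal proteins (0.10, adjusted p = 0.448) and skin keratinocyte genes (0.11, adjusted p = 0.935), whose medians change sign with the scaling. Leaving out 1 mix moved many of the medians in this paragraph. Without mix 1 lung stood at 1.12, lymphoid -0.18, yolk -0.19, smooth muscle 0.37, fatty acid oxidation 0.20 and liver transcription factors -0.87. Without mix 2 amino acid catabolism stood at -0.18, fatty acid oxidation 0.20, endocrine -1.03 and lung genes 0.35. Without mix 3 complement stood at -0.04, keratinocyte -0.08, fatty acid oxidation -0.28, smooth muscle -0.40 and mitochondrial genes 0.02. Without mix 4 lymphoid stood at -0.66, testis -0.42, cholesterol -0.18 and macrophage genes 0.03. For macrophage genes (0.25, adjusted p = 0.796) and keratinocyte genes the mean, at -0.22 and -0.04, was opposite in sign to the median. When adjusted over the list alone 4 complement genes, 1 gene of amino acid catabolism and 1 lung gene passed limma, and 0 over all.

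A set of 248 probe sets, naming 143 genes, was at least 4-fold brighter on adipose than on each of the other 5 arrays. The widest margins belonged to C12orf75 (4204 against at most 144), COL28A1 (2516 against at most 96.9), HPS4 (2159 against at most 83.8) and FAM57A (1446 against at most 59.1). HOPX (11723), PLIN1, the receptor kinase RET (4273 against at most 275), PI16 (2198), C27H17ORF105 and LPL followed. Of the fixed lists, 8 of 25 adipocyte genes belonged to the set (CD36, G0S2, LPIN1, LPL, PLIN1, PNPLA2, PPARG and RBP7), with 6 of 18 genes of triglyceride storage, 4 of 41 fibroblast and matrix genes (ELN, MFAP5, OGN and PI16), and 3 of 21 endothelial genes (CLDN5, FABP5 and PECAM1). It also held 3 of 10 lung genes (HOPX, SFTPA1 and SFTPA2) and 2 of 18 genes of fatty acid synthesis (ACACB and SCD). FABP4, the brightest of the named fat-cell genes at 18285, was not among them, with mix 3 at 4810.2. Over all probe sets 26.9% lay above all 4 mixes on adipose and 15.7% below. The shares were 22.3% and 18.9% with quantile, 18.8% and 24.4% with trimmed-mean and 21.8% and 19.5% with spike-in scaling. The rule of 4-fold above each of the other 5 arrays gave 321, 142, 107 and 730 probe sets on mix 1, 2, 3 and 4. The size of the adipose set is therefore not particular to adipose.

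By limma 13 probe sets passed on liver against the mixes at an adjusted p under 0.05 (5165 at an unadjusted p under 0.05), all higher on liver and above all 4 mixes. That test measures the liver array against the spread among the 4 mixes, which are not replicates of each other, and carries no spread of liver itself. The probe sets that passed are faint on the mixes (1 to 72.4). They include the complement component C8A (3175 against 6.17 ± 3.47, mean ± SD, n = 4, log2 difference 7.40, SE 0.48, adjusted p = 0.0426), the kininogen KNG1 (6956 against 29.4 ± 10.5, 7.39, SE 0.44, adjusted p = 0.0426) and the coagulation inhibitor SERPINA10 (6174 against 27.2 ± 13.9, 7.33, SE 0.55, adjusted p = 0.0426). TDO2, the first enzyme of tryptophan breakdown, was higher by 7.01, the beta-defensin AvBD8 by 6.81 (3.14 by its other probe set) and MRAP, a partner of melanocortin receptors, by 5.65. SPIA4 was higher by 6.84, SPIA5 by 6.63, SULT by 6.34, LOC101748207 by 8.15 and LOC423629 by 7.50. Floored at 44.1, LOC101748207 stood at 6.98, SPIA4 6.22, C8A 6.17 and LOC423629 6.11. The last of the 13 are a probe set of A2ML4 (7.06) and AWAT1 (5.43), which the rule for naming genes does not reach and which were chosen after their values were seen. Adjusted p was 0.0426 for all but SULT (0.0448). Relative to the -0.75 of all probe sets each of these is larger by that amount, an offset that does not correct for the level of the array. ALB, the main plasma protein, gave 15031 against 1756 ± 2102 (4.15, adjusted p = 0.267) and FGB 14452 against 1313 ± 2007 (5.52), and neither passed. Without mix 1, 2, 3 or 4 in turn 0 probe sets passed (4376, 4268, 4731 and 4263 at an unadjusted p under 0.05), with adjusted p = 0.123, 0.207, 0.165 and 0.0757 to 0.099 for the 11 genes named by that rule. Their differences stayed at 5.52 to 8.21 in these fits. With the smaller pseudocount at the pooled 10th percentile 0 passed (5886 at an unadjusted p under 0.05).

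As lists, the functions of the hepatocyte were higher on liver, with medians relative to all probe sets in brackets. The brackets are no correction for array level. Medians of the plasma protein, complement and amino acid lists were 5.6, 3.9 and 3.6 with quantile scaling. With trimmed-mean scaling they were 6.2, 4.4 and 4.1, all under their brackets. For fatty acid synthesis quantile scaling gave 2.3, near its bracket. Of 36 plasma protein genes 34 lay above all 4 mixes (median 5.61 [6.36], FGA 7.61, ITIH3 7.60). Of these genes 2 passed over all probe sets and 24 when adjusted over the list alone (camera adjusted p = 2.89e-51, and adjusted p = 0.112 with an estimated correlation). Of 16 complement genes 13 lay above all mixes (3.83 [4.58], MBL2 7.41, C8B 7.01, C5 5.97, or 2.06 by its other probe set). Of these genes 1 passed over all and 13 when adjusted over the list alone (adjusted p = 1.02e-25, or 0.112 with an estimated correlation). Of 37 genes of amino acid catabolism and gluconeogenesis 25 lay above all mixes (3.49 [4.24], TAT 7.94, HPD 6.25, HAL 6.03). Of these genes 1 passed over all and 18 when adjusted over the list alone (adjusted p = 1.97e-30, or 0.203 with an estimated correlation). Several genes named here are faint on the mixes, and floored at 44.1 FGA stood at 7.30, MBL2 7.06, TAT 6.99, C8B 6.63, HAL 5.07 and NR1H4 2.83. Bile acid and xenobiotic metabolism followed, with 18 of 31 genes above all mixes (1.92 [2.67], the bile salt pump ABCB11 3.45, the receptor NR1H4 3.47). In that list 0 passed over all and 5 when adjusted over the list alone (adjusted p = 1.88e-20, or 0.203 with an estimated correlation). Macrophage genes were higher as well, with 10 of 18 above all mixes (1.18 [1.93], the uptake receptors TIMD4 3.89, MARCO 3.58 and MRC1 3.14). Of them 0 passed over all and 7 when adjusted over the list alone (adjusted p = 5.97e-12, or 0.203 with an estimated correlation).

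Fuel metabolism was higher on liver too. De novo fatty acid synthesis had 11 of 18 genes above all mixes (1.57 [2.32], THRSP 4.83, the elongase ELOVL6 4.37 with 2.22 by the lowest of its 3 probe sets, FASN 2.80). Of them 0 passed over all and 7 when adjusted over the list alone (adjusted p = 4.73e-11, or 0.203 with an estimated correlation). Fatty acid oxidation and ketogenesis had 14 of 21 above (1.16 [1.90], EHHADH 2.78, ACAT1 2.23, adjusted p = 3.47e-12, or 0.373 with an estimated correlation), and 0 passed over all and 1 when adjusted over the list alone. Liver transcription factors had 6 of 11 (1.24 [1.99], CREB3L3 3.45, adjusted p = 4.91e-07, or 0.359 with an estimated correlation) and cholesterol synthesis 5 of 15 (0.44 [1.19], HMGCS1 4.10, adjusted p = 1.17e-05, or 0.55 with an estimated correlation). None of the genes of these last lists passed in either count. Mitochondrial respiration (0.19 [0.94], adjusted p = 1.38e-07, or 0.634 with an estimated correlation), triglyceride storage (0.33 [1.07], adjusted p = 0.00171, or 0.203 with an estimated correlation, 0.0698 with quantile normalization in a range of 0.000345 to 0.0698) and the 2 yolk protein genes measured (1.04 [1.79], APOV1 at 69.7, adjusted p = 0.00636, or 0.203 with an estimated correlation) were higher by less, again with no gene past either count. Adipocyte genes passed upward (adjusted p = 0.000285, or 0.203 with an estimated correlation) on a median of -0.20 [0.55] and a mean of -0.14, and that median is 0.49 with quantile and 0.24 with trimmed-mean scaling. In it 1 gene passed over all (MRAP) and 4 when adjusted over the list alone, with THRSP high as well while LPL (-3.24) and ADIPOQ (-4.28) stood low. Intestine genes passed upward (adjusted p = 0.015, or 0.997 with an estimated correlation) although 20 of 28 were lower (median -1.19 [-0.44]), with TM4SF4 (5.45, or 1.38 by its other probe set), APOA4 (4.43) and FABP1 (4.16) far higher. That call ended without mix 4 (0.158) and with spike-in (0.0845), trimmed-mean (0.745) and quantile scaling (0.871, with the direction turned), in a range of 0.000156 to 0.871. Without mix 1 that median was 0.01. Without mix 3 the medians of cholesterol synthesis, mitochondrial respiration and adipocyte genes were 0.13, 0.00 and -0.01, and without mix 4 that of cholesterol synthesis was 0.79 and without mix 2 that of adipocyte genes -0.32.

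Dividing-cell and connective-tissue genes were lower on liver, where 60.5% of all probe sets lay below all 4 mixes. Of 35 cell cycle genes 34 lay below all 4 mixes (-1.85 [-1.10], NUSAP1 -3.06, TPX2 -2.96, TYMS -2.95). Of them 0 passed over all and 22 when adjusted over the list alone (adjusted p = 4.91e-07, or 0.634 with an estimated correlation). Of 41 fibroblast and matrix genes 35 lay below (-1.87 [-1.12], THY1 -4.63, BGN -3.94, VIM -3.61). Of them 0 passed over all and 10 when adjusted over the list alone (adjusted p = 0.00121, or 0.555 with an estimated correlation). With quantile, trimmed-mean and spike-in scaling 27, 29 and 33 cell cycle genes and 29, 29 and 33 matrix genes lay below. Among the largest single decreases in value, in an order that depends on the pseudocount, were those of EEF1A2, the elongation factor of muscle and nerve (-6.34), MB (-6.25), MME (-5.97, adjusted p = 0.0537, range over the alternatives 0.0369 to 0.207), MYL10 (-5.62), COL11A1 (-5.41, -1.56 by the nearest to 0 of its 5 probe sets) and COMP (-5.41, -3.20 by the nearest to 0 of its 3), and none passed. On liver they gave 8.4, 3.2, 14.2, 8.1, 2.2 and 30.5, and floored at 44.1 stood at -5.28, -4.75, -5.26, -4.50, -3.79 and -5.37. MME alone passed with some alternatives: the median as pseudocount (0.0377), the floor (0.0478), no filter (0.0478), and quantile (0.038) and trimmed-mean scaling (0.0369). THY1 and BGN, at 5.4 and 11.3 on liver, stood at -3.30 and -3.13 with the floor. The other 15 lists did not pass. Ribosomal proteins had a median of -0.37 [0.38] (adjusted p = 0.99, range over the alternatives 0.000123 to 0.843), with 56 of 57 genes lower, and 0.23 with trimmed-mean scaling. They passed downward with quantile scaling (0.000123) and the floor (0.0166) and upward with trimmed-mean scaling (0.000531). Skeletal muscle had -2.67 (adjusted p = 0.411, range 0.000123 to 0.98, 0.000443 without mix 1, 0.000123 with quantile and 0.00148 with trimmed-mean scaling) and pancreas -3.48 (0.93, range 0.0259 to 0.978, 0.0259 with quantile scaling). Skin keratinocyte genes (-0.45, 0.058, range 0.0354 to 0.361, 0.0354 without mix 1, 0.0428 without mix 2, 0.0425 with the 10th percentile as pseudocount, 0.0494 with the floor and 0.0466 with the mean of all probe sets), endothelium (-0.50, 0.335) and lymphoid genes (-0.64, 0.801) have medians that change sign with the scaling. The rest were testis (-1.28, 0.544), smooth muscle (-1.56, 0.676), red-cell (-1.97, 0.93), glandular stomach (-2.70, 0.469), heart (-1.37, 0.718), brain (-1.80, 0.676), kidney (-1.17, 0.512), endocrine gland (-2.29, 0.645) and lung genes (-0.96, 0.801). Single mixes carried some of these medians: without mix 1 stomach stood at -1.17 and keratinocyte genes at -0.22, and without mix 2 pancreas at -1.74, heart at -0.44 and kidney at -0.67. Red-cell genes stood at -1.07 without mix 3 and brain at -0.68 without mix 4. When adjusted over the list alone 1 endothelial gene passed, and 0 over all. For the stomach, heart, brain, kidney, endocrine, lung, lymphoid, endothelial and keratinocyte lists the median is below 0. Camera, which compares a list with all other genes, points upward there. Relative to all probe sets the medians of the lymphoid, endothelial and keratinocyte lists lie above 0 (0.11, 0.24 and 0.29). Those of the stomach, heart, brain, kidney, endocrine and lung lists stay below 0 (-1.95, -0.62, -1.05, -0.42, -1.54 and -0.21). For these camera's direction is opposite to that of the median, also when set against all probe sets.

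A set of 237 probe sets, naming 165 genes, was at least 4-fold brighter on liver than on each of the other 5 arrays. By the margin over the next array, which near the floor depends on the pseudocount, LOC101748207 came first (5567 against at most 9.5), followed by NME4 (9029.9 against at most 46.2, while the lowest of its 4 probe sets stood at -1.31), KNG1, C8A, LOC423629, SERPINA10, SPIA4, TAT (5909 against at most 53.8), TDO2 and LOC771012 (9497 against at most 100). With all values floored at 44.1 the margin of LOC101748207 was 6.98, under NME4 (7.61), KNG1 (7.28) and SERPINA10 (7.09), and C8A, LOC423629 and SPIA4 stood at 6.17, 6.11 and 6.22. The set held 24 of 36 plasma protein genes, 18 of 37 genes of amino acid catabolism and 8 of 16 complement genes. It also held 5 of 31 genes of bile acid and xenobiotic metabolism (ABCB11, CYP27A1, CYP7A1, CYP8B1 and SLCO1B3), 3 of 18 macrophage genes (HMOX1, MARCO and TIMD4), and MRAP, ELOVL6 and HMGCS1. ALB was not among them, with mix 4 at 4698, nor was APOA1, at 13277 on liver and 12477 on mix 1. Over all probe sets 6.78% lay above all 4 mixes on liver and 60.5% below under the deposited scaling. The shares were 23.1% and 27.8% with quantile, 17.6% and 35.8% with trimmed-mean and 8.32% and 54.4% with spike-in scaling. The count of 237 lies within the 107 to 730 that the same 4-fold rule gave on single mixes.

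Set directly against each other, the adipose and liver arrays were separated most by plasma proteins on one side and matrix, vessel and fat-storage genes on the other. The fibrinogen chain FGA gave 14803 on liver and 3 on adipose (log2 adipose minus liver -9.85), with LBFABP (-9.75), FGG (-9.71), ORM1 (-9.69), AHSG (-9.64), AMBP (-9.41), APOA4 (-9.40) and FABP1 (-9.31) close behind. All 8 gave 1 to 6.5 on adipose, under the pseudocount of 13, so size and order depend on it. With both sides floored at 44.1, which leaves a bound, the differences were -8.39, -8.28, -8.51, -8.17, -7.98, -7.96, -8.22 and -8.10 in that order. On the adipose side stood LPL (10403 against 32.2, 7.85), RBP7 (7.58, or 1.55 by its other probe set), C12orf75 (7.32), FABP4 (7.23), MXRA5 (7.15), FABP3 (7.10), RET (7.03) and CDH13 (7.02). On liver LPL, C12orf75, MXRA5, RET and CDH13 gave 32.2, 13.3, 2.8, 19.7 and 22.5, and at that floor stood at 7.88, 6.58, 5.67, 6.60 and 6.71. All 41 fibroblast and matrix genes were higher on adipose, 33 of them at least 4-fold (median 3.39, percentile 100 among 10000 random lists of like expression). Endothelial genes were higher in 20 of 21 (2.20, percentile 100), triglyceride storage genes in 13 of 18 (1.72, percentile 99.98), adipocyte genes in 21 of 25 (1.69, percentile 99.99) and smooth muscle genes in 15 of 18 (1.55, percentile 99.89). Plasma proteins were higher on liver in 35 of 36 (-7.40), genes of amino acid catabolism in 31 of 37 (-3.95), and complement in 12 of 16 (-3.02). So were bile acid metabolism in 28 of 31 (-2.94), liver transcription factors in 10 of 11 (-2.74), fatty acid oxidation in 17 of 21 (-1.05) and macrophage genes in 15 of 18 (-1.01), all of them at percentile 0 among random lists. Also at percentile 0 were cholesterol synthesis (-0.77, higher on liver in 11 of 15), de novo fatty acid synthesis (-0.47, 12 of 18), intestine (-0.40, 17 of 28) and mitochondrial respiration (-0.00, 20 of 40). The random lists carry the shift of all probe sets toward adipose (median 0.78). A list that is level between the arrays, such as mitochondrial respiration, can therefore lie at percentile 0. FASN was bright on both arrays, at 3132 and 4515. In all, 3835 probe sets differed at least 4-fold, 3123 higher on adipose and 712 on liver. That 81.4% share for adipose was 51.9% with quantile (1320 against 1222), 54.3% with trimmed-mean (1402 against 1181) and 74.1% with spike-in scaling (2389 against 837), and the median of all probe sets was 0.78 higher on adipose. The medians of the brain, pancreas, kidney, lymphoid, endocrine, red-cell, keratinocyte and ribosomal lists change sign with the scaling. With 1 array on each side these differences have no replicate check.

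**Figure D3:**
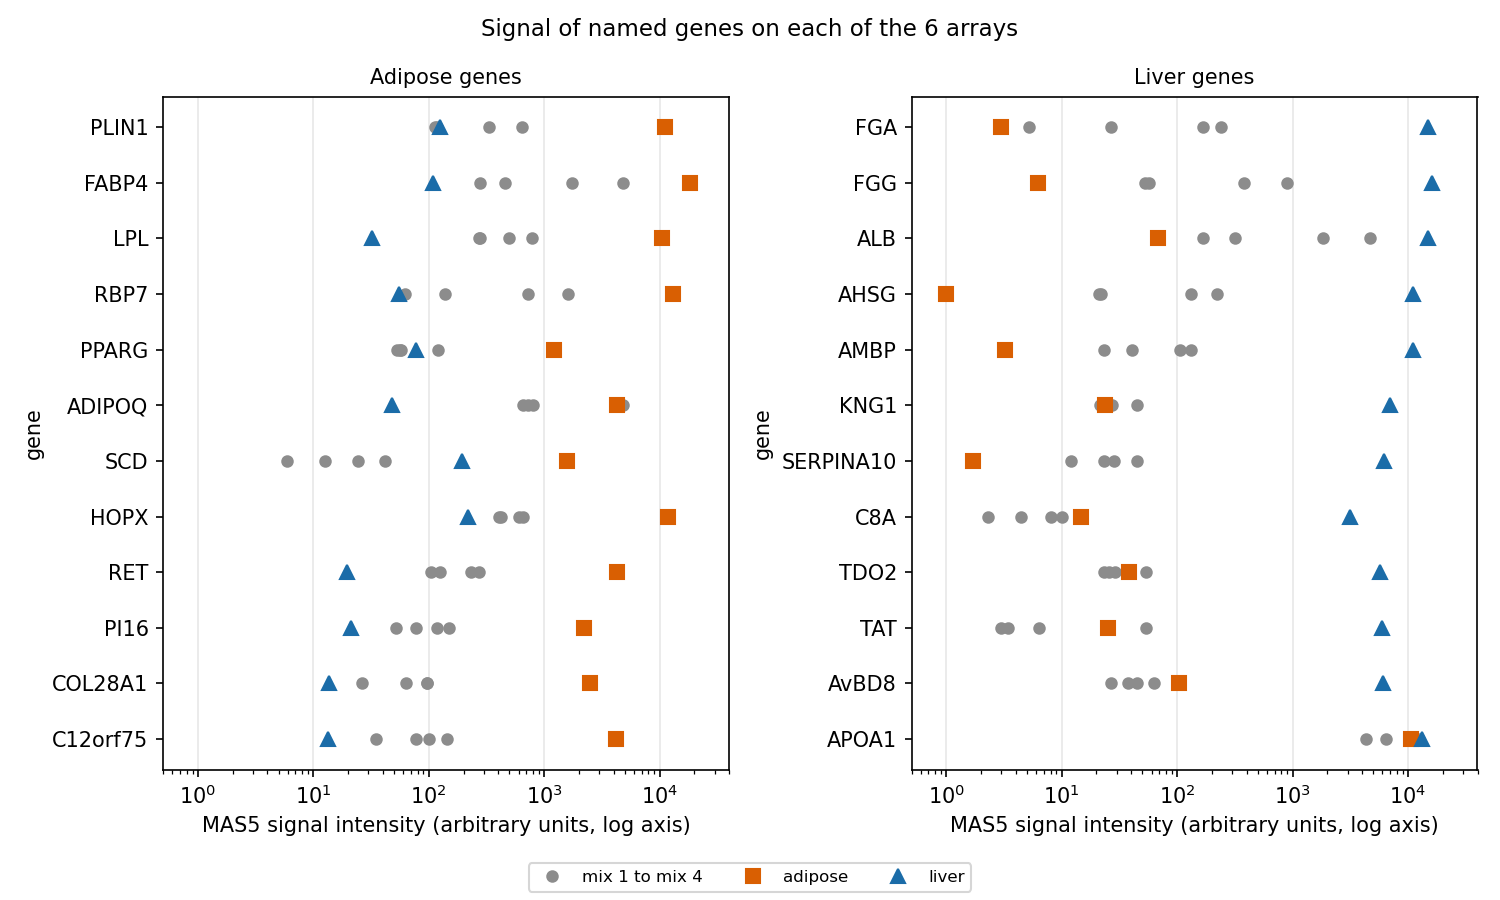
Signal (log10 axis) of named genes on each of the 6 arrays, with adipose genes on one side and liver genes on the other and 1 point per array. PLIN1 reaches 11033 on adipose and KNG1 6956 on liver, while ADIPOQ is as bright on mix 1 (4824) as on adipose (4236).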

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

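Each test of an explanation in this part was chosen only after the result it weighs was seen. With 4 mixes, a result is listed here when the gap between the highest or lowest mix and the nearest other mix takes up more of the whole range than Dixon's critical value; chance alone gives this for about 1 in 20 results. It was met by 3 of 31 lists and 6 of 53 named genes, and among all probe sets by 1821 (7.02%), with mix 1 apart in 423, mix 2 in 280, mix 3 in 429 and mix 4 in 689.

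The share of the range was 0.896 for ADIPOQ (log2 level 12.24 on mix 1 against a mean of 9.52 on the others). It was 0.914 for the median of the brain list, at 10.18 on mix 4 against 5.87. It was 0.941 for the complement list, at 6.92 on mix 1 against 7.56, and 0.958 for the fibroblast and matrix list, at 9.14 on mix 2 against 10.29. PPARG was higher on mix 3 (0.91; 7.05 against 6.10) and SPIA4 lower there (0.865; 4.29 against 5.04). LOC423629 (0.852; 4.67 against 3.89), NME4 (0.854; 5.89 against 4.19) and TAT (0.869; 6.06 against 4.10) were higher on mix 4; all 3, and SPIA4, lie near the floor on the mixes.

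The brain list belongs to a wider pattern: the 4 mixes differ among themselves about as much as they differ from adipose (mean r 0.783 and 0.798). Differences in the overall signal distribution of the arrays, such as those of scaling, are argued against as the main cause. The median SD over the mixes kept 0.98 of its size after quantile normalization (0.973 to 0.986 over 1000 bootstrap draws). Those draws resampled probe sets on the same 4 arrays and carry no spread between arrays. The spike-ins had a median SD of only 0.13. Differences in hybridisation that affect single probe sets would remain after quantile normalization, so that ratio cannot decide on them. Each mix holding different tissues goes with the lists: for 14 of the 17 tissue lists the range between the mixes was above the 95th percentile of 1000 random lists, the exceptions being lung, endothelium and skin keratinocyte. That is a hypothesis found on the same data, since the labels do not say what a mix holds.

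ADIPOQ is as bright on mix 1 (4824) as on adipose (4236). Adipose tissue in mix 1 is argued against as the source, since the median difference, mix 1 minus adipose, of the 12 other adipocyte genes with a signal over 1000 on adipose was -5.19 (quartiles -6.10 and -3.66), where ADIPOQ itself has 0.19. Another transcript in mix 1 that binds the probe set could give the signal; with 1 ADIPOQ probe set on the array no second measurement decides, and this stays open. No biological explanation was tested.

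Some lung genes are brightest on the adipose array: SFTPA1 gave 2228, SFTPA2 2013, NKX2-1 102 and HOPX 11723 there, against at most 471, 421, 60.9 and 656 on the other arrays. These 4 genes were picked after their values were seen. Lung tissue in the adipose sample could bring them. Of the 6 other lung-list genes 1 (LAMP3, 73.9 against at most 45) was brighter on adipose than on each other array and none passed a signal of 200 on adipose (highest 146.8), too near the floor to decide, so this stays open beside expression in adipose tissue itself, which was not tested. SNTN (140.5) and TPPP3 (1218), also picked after their values were seen, were at least 4-fold brighter on adipose than elsewhere.

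The lower signal of the liver array was also looked at, with tests that are given as values only. Against the mixes the spike-ins lay at -0.12 (quartiles -0.24 and -0.06) and all probe sets at -0.75. The 100 brightest probe sets held 13.8% of the signal on liver and 9.14% to 12.4% on the mixes; the share outside the 1000 brightest was -0.307 (log2) relative to the mixes (-0.403 to -0.264). The ratio of 3' to 5' signal was 1.85 for actin, 1.05 for GAPDH and 1.56 for EF1A on liver, above all mixes for the last alone.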

How the results depend on the processing

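Trimmed-mean and spike-in scaling were chosen after the data were seen. For counts and correlations that answer a comparison 73 values stayed close and 24 moved, all of which are given here. Of list results 686 kept their call or stayed close, 26 passed only there and 55 no longer passed. The direction changed in the rest: 37 moved, with no pass in either fit, and 2 turned, with a pass in either fit. Of 4156 values of named genes under the alternatives, 3965 kept their side of the threshold or stayed within the spread. Another 90 moved, 46 passed a threshold only there and 55 no longer passed. For named genes compared with the mixes, moved likewise means that the direction changed with no pass in either fit. For adipose against liver it means a shift beyond the spread. Among values of named genes that passed in either fit, or lay at least 4-fold apart between adipose and liver, 0 changed direction. Where no reason is given below, the cause was not tested.

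Adipose against the mixes gave 0 probe sets under every setting but the floor at the pooled median, with 671 (670 higher); all 4 mixes sat at the floor in 420 of them, where the floor leaves no spread. Liver against the mixes gave 0 with the pooled 10th percentile as pseudocount, 84 with the median, 204 with the floor (143 with all mixes at it), 27 without the filter, 50 with quantile normalization, 79 with trimmed-mean scaling and 28 without a trend. Each of these counts other than 0 held the same 13, as did the 17 with spike-in scaling. Without mix 1, 2, 3 or 4 the count was 0 to 0, with fewer arrays.

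Adipose against liver at 4-fold gave 2224 with the median as pseudocount, which shrinks differences near the floor, and 2542 with quantile normalization. By construction, it gave 12181 at 2-fold and 1366 at 8-fold. Limma with the spread of the mixes gave 0 (5348 at an unadjusted p under 0.05). The adipose-prominent set held 1088 at 2-fold, 66 at 8-fold and 260 to 360 without 1 mix; the liver-prominent set 466, 136 and 240 to 311. Mean r between mixes was 0.862 without the filter, where faint probe sets enter on all arrays.

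With an estimated correlation 0 lists passed for adipose and 0 for liver (3 and 6 unadjusted), against 16 each. Without 1 mix 16 to 19 passed for adipose and 15 to 18 for liver. The intestine list on liver turned with quantile normalization (adjusted p = 0.871), and the ribosomal protein list turned upward with trimmed-mean scaling (adjusted p = 0.000531).

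No paired analysis was possible because the groups share fewer than 2 replicate numbers. Signal over background limits genes faint on the mixes, whose differences depend on the pseudocount.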

Other observations

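The genes in this part were chosen after their values were seen, and so was the random-list comparison. All 5 measured of 6 genes asked for in purine synthesis were at least 4-fold brighter on liver than on each other array: PPAT 6948 (log2 liver minus mixes 3.39), GART 6192 (4.59), PAICS 8507 (3.28), ADSL 8065 (3.22) and ATIC 13276 (3.16). Their median of 3.28 lay at percentile 100 among 10000 random lists of like expression, a comparison that cannot be independent of how they were picked. Around that pathway, PRPS2, which makes its starting substrate, gave 11597 (6.33), the folate enzymes MTHFD1 5556 (3.90) and SHMT1 2367 (5.50), and XDH, which turns purines into uric acid, the main nitrogen waste of birds, 2002 (3.59).

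On adipose, the caveolae genes CAV1 (1598; log2 adipose minus mixes 4.32) and CAV2 (7466; 3.19), the fatty acid ligase ACSL1 (6778; 4.49), the endothelial receptor ADGRL4 (1448; 3.43) and the transcription factors MEOX2 (2723; 3.49) and EBF3 (576; 2.74) were each at least 4-fold brighter than on any other array.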
